A study of Mus musculus with 6 samples.

How the data were processed

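Messenger RNA of the hippocampus of 6 C57BL/6J mice, 3 on control diet and 3 on ketogenic diet for 3 weeks, was measured by sequencing Illumina TruSeq libraries made from 1 µg of total RNA, per the labels' protocols. The extraction protocol names retina, while the tissue label and the treatment protocol name hippocampus. Of 26 listed retina markers 6 had enough counts to test, and the libraries were treated as hippocampus. The diet of each library was taken from its label. Each diet has 3 libraries numbered 1 to 3, from 6 mice per the labels, and no label says that a number marks a litter, cage or day.

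The authors deposited raw read counts per Ensembl gene and FPKM values (fragments scaled by gene length and library size), each for all 6 libraries. Per the submitters' processing notes, the tools were CASAVA, featureCounts 1.5.0-p3 and DESeq2 1.10.1 and the build mm9. The aligner, the strand setting and the tool that made the FPKM values are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. Of 53620 gene identifiers shared with GENCODE release M21, which is on GRCm38, 97.1% have the same start and end there, so the printed coordinates were taken to be on GRCm38 (mm10) and not mm9. The deposited FPKM values were checked on genes with more than 50 counts, and equal the count over gene length over 1 library size per sample. That size was between 0.987 and 1.02 times the total count. Divided by the library's DESeq2 size factor it was nearly constant, from 1.726e+07 to 1.735e+07. It thus followed these factors more closely than the total count.

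The counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the diet groups, which left 16478 of 53715. Libraries were scaled by TMM, and a quasi-likelihood F-test compared ketogenic with control diet without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The standard error is the size of the log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. Totals of 16832240 to 18357792 counts per library gave a median standard error of 0.13 on the log2 fold change, with a common biological coefficient of variation of 11.6%. The 42 gene lists, the main tests, the naming rule and the alternatives of the first group below were fixed before the data were examined. The lists hold pathways a ketogenic diet could touch and markers of cell types and neighbouring regions that a dissection could hold. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 42 lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Of the listed symbols, 7 had no row in the count table.

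The naming rule takes Nrg1 and Erbb4 with each library's value, and Nrg2, Nrg3, Erbb2 and Erbb3. Of genes past the threshold with a mean of at least 1 CPM and no overlap between the diets it takes the 10 largest rises and the 10 largest falls, leaving out clone and model names. From each list past the camera test, or with members past the threshold, it takes up to 4 members by smallest p, from lists of GABA, ketone body, fatty acid oxidation and sterol genes up to 3 whether or not they passed, and from cell type lists the 2 most abundant members. In lists not past the camera test, members taken only for their p that missed the threshold are mostly not named, a departure from the rule. Some genes that the rule takes are not reported here. Slc12a2, Slc32a1 and the genes of the ventral and dorsal hippocampus lists were named after values were seen.

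The steps were tested on simulated data, with counts drawn for 16478 genes from the means and library sizes of this comparison. There edgeR recovered 70 of 100 genes changed 1.5-fold and 94 of 100 genes changed 2-fold, with 19 false calls, and camera called 0 of 42 lists without a planted effect. The simulated genes varied independently of each other. The simulation therefore does not test camera's preset correlation on lists whose genes vary together. Alternatives of this first group were RLE and upper-quartile scaling, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a replicate block, each library left out in turn, and other thresholds. Chosen after seeing the data were fits with the choroid plexus or dentate list mean as a covariate, without control 1 and 2, and without marker genes (137 listed genes, with Nrg1 and Erbb4 kept), and the added lists of ventral and dorsal hippocampus markers and of Gad1, Gad2 and Slc32a1.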

Results

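Hippocampal messenger RNA was profiled in 6 adult male mice of the inbred strain C57BL/6J, aged 2 to 3 months. Of these, 3 had eaten a control diet and 3 a ketogenic diet, a high-fat, low-carbohydrate diet that raises circulating ketone bodies, for 3 weeks. The libraries are called control 1, 2 and 3 and ketogenic 1, 2 and 3. Gene counts summed to between 16832240 and 18357792 per library over 53715 annotated genes, of which 16478 had enough counts to test. Libraries of the same diet differed by more than counting noise, with a chi-square per degree of freedom between 6.26 and 18.8, and each was used as a separate replicate. Levels are CPM, gene counts scaled to a common library size, as mean ± SD (n = 3 per diet). Changes are ketogenic over control on the log2 scale, with their standard error after ±, and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 16478 genes. The first principal component, with 49.6% of the variance, separated the diets, with control libraries at -40.7, -30.2 and -12.2 and ketogenic libraries at 18.5, 31.4 and 33.1.

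The first question was which genes differed between the diets. With camera's preset correlation, lists of interneuron, subicular and fibroblast marker genes passed upward in the ketogenic libraries, and lists of choroid plexus, myelin, dentate granule cell and CA3 marker genes passed downward. None of these lists passed with an estimated correlation (adjusted p between 0.181 and 0.314). In all, 1593 genes passed the test, 832 higher and 761 lower with the ketogenic diet. Of these, 255 had a log2 fold change of at least 1 and 141 of -1 or less. The diets did not overlap in 1582 of the 1593 genes, and in 27.6% of all tested genes, where chance gives 10%. All 127 genes past the threshold that the naming rule picked were separated in this way, which the rule requires of the 10 largest rises and 10 largest falls and favours by taking other genes by smallest p. The median log2 fold change of all tested genes was -0.01. The count fell to 677 without control 2, 538 without ketogenic 2 and 885 without ketogenic 3, of which 657, 531 and 843 were among the 1593. With control 1 and 2 left out, the libraries with the most choroid plexus transcripts, 289 genes passed, in a comparison added after seeing the data in which the lone control library is assumed to vary like the others.

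The series is about Nrg1 and its receptor ErbB4, and both genes rose. Erbb4 encodes a receptor tyrosine kinase that in the forebrain is found mainly in GABAergic interneurons (ENSMUSG00000062209, chromosome 1, 68032186 to 69108059, minus strand, coordinates as deposited, which match GRCm38). It rose from 60.1 ± 2.93 to 94.4 ± 19.1 CPM, a log2 fold change of 0.65 ± 0.13 (adjusted p = 0.0116). The control libraries had 57.3, 63.1 and 59.8 CPM and the ketogenic libraries 73.7, 98.1 and 111.2 CPM. Nrg1 encodes the growth factor neuregulin 1, a ligand of ErbB4 (ENSMUSG00000062991, chromosome 8, 31814551 to 32884029, minus strand). It rose from 3.40 ± 0.568 to 6.24 ± 1.48 CPM, a log2 fold change of 0.87 ± 0.23 (adjusted p = 0.0389), with 2.78, 3.90 and 3.51 CPM in the control libraries and 4.64, 6.55 and 7.55 CPM in the ketogenic libraries. In 15 alternatives set beforehand the call of Erbb4 was lost without ketogenic 2 (adjusted p = 0.0659) and on log2(FPKM + 1) values (adjusted p = 0.0509). The lowest adjusted p of Erbb4 were 2.32e-09 without a filter and 1.09e-05 with DESeq2. Without a filter 30524 genes were tested, and the log2 fold change of Erbb4 was the same at 0.65. That lower p therefore comes from the fit to more genes and is no stronger evidence of a change. The call of Nrg1 was lost in 8 of these 15, over a range of 0.00309 to 0.146, with adjusted p of 0.116, 0.0827 and 0.0574 without control 1, 2 and 3, 0.146 and 0.139 without ketogenic 2 and 3, 0.0584 with limma-voom, and 0.115 and 0.117 on log2(FPKM + 1) and log2(FPKM + 0.1) values. Of 4 fits chosen after seeing the data both calls were kept in 1, with marker genes left out, at 0.65 for Erbb4 and 0.87 for Nrg1 (adjusted p = 0.0106 and 0.0383), and lost in the others. Leaving out other genes does not change the counts of Erbb4 and Nrg1, so that fit cannot test a difference in tissue content. Diet accounts for 78.6% of the variance of the dentate list mean and 81.3% of that of the choroid plexus list mean. Fits with either mean as a covariate, here and below, can therefore hardly separate tissue content from diet. With the dentate list mean as a covariate the log2 fold changes were 0.041 for Erbb4 and 0.19 for Nrg1 (adjusted p = 0.966 and 0.929), and with the choroid plexus list mean 0.69 and 0.72 (0.457 and 0.715). With control 1 and 2 left out they were 0.66 and 0.83 (adjusted p = 0.137 and 0.280).

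**Figure D1:**
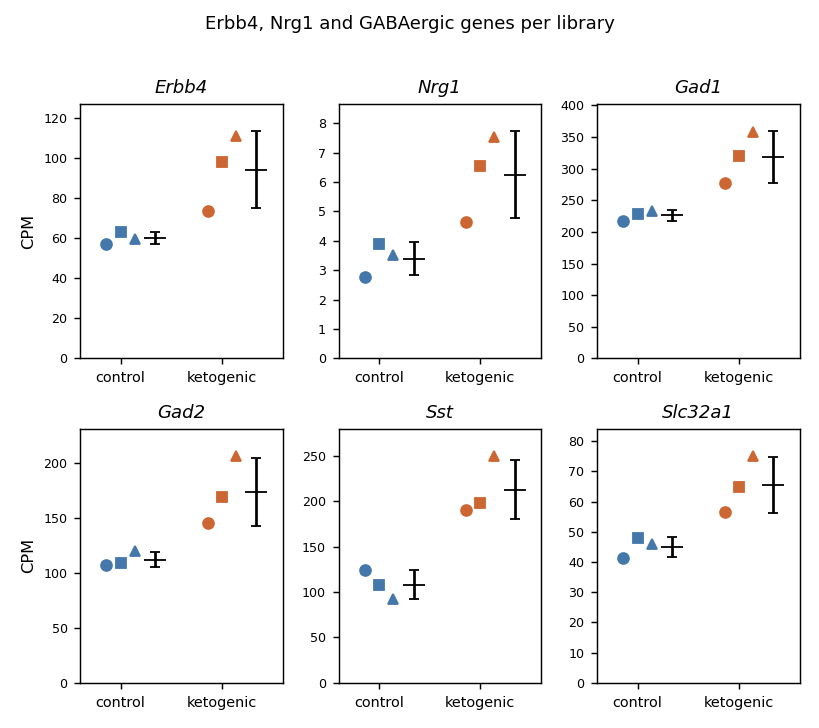
CPM (vertical axes) of Erbb4, Nrg1 and 4 genes of GABAergic neurons in the 3 control and 3 ketogenic libraries, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD (n = 3). In Erbb4 the ketogenic libraries lie at 73.7 to 111.2 CPM and the control libraries at 57.3 to 63.1 CPM.

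Of the 20 tested genes of ErbB receptors, ligands and partners, 3 rose (Erbb4, Nrg1 and Lrig1) and 2 fell (Erbin and Erbb3), and adjusted over the list alone 4 were higher and 4 lower. The list as a whole was not past the camera test (adjusted p = 0.809), with a mean of -0.01 and a median of 0.04. Erbb3, a receptor gene expressed in glia, fell by 0.62 on the log2 scale (adjusted p = 0.0497), from 14.9 ± 3.39 to 9.68 ± 0.842 CPM. Erbin, whose product binds ErbB2, fell by 0.53 (adjusted p = 0.0243), and Lrig1, a negative regulator of ErbB receptors, rose by 0.49 (adjusted p = 0.0321). Nrg2 stood at -0.56 (adjusted p = 0.0913), Nrg3 at 0.06 (adjusted p = 0.685) and Erbb2 at -0.16 (adjusted p = 0.745). In the same libraries the interneuron markers had a mean log2 fold change of 0.69. The myelin markers, which include Enpp2, a gene also abundant in choroid plexus, had a mean of -0.83 and a median of -0.76. The call of Erbb3 was lost without any library but control 3 (adjusted p up to 0.160), that of Erbin without control 1, control 2, ketogenic 2 or ketogenic 3 (up to 0.124) and that of Lrig1 without control 2, control 3, ketogenic 2 or ketogenic 3 (up to 0.137). With the choroid covariate the log2 fold changes of Erbb3 and Erbin turned to 0.14 and 0.11 (adjusted p = 0.934 and 0.910).

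Many markers of GABAergic interneurons rose. Of 29 tested interneuron markers, 19 rose and none fell, and adjusted over the list alone 20 were higher. The list passed the camera test (adjusted p = 1.84e-21; adjusted p = 0.30 with an estimated correlation). Its mean log2 fold change of 0.69 became 0.25 with the dentate covariate and 0.66 with the choroid covariate, with the call kept in both (camera adjusted p = 0.00079 and 1.58e-08). Calb2, the calretinin gene, rose from 7.46 ± 1.11 to 53.4 ± 7.96 CPM, a log2 fold change of 2.84 ± 0.15 with the smallest p of all tested genes (adjusted p = 3.14e-05). Sst, the somatostatin gene, rose by 0.98 ± 0.12 (adjusted p = 0.00179), Kit by 0.83 ± 0.11 (adjusted p = 0.00207) and Nxph1 by 0.86 ± 0.14 (adjusted p = 0.00468). Cck, the most abundant member, stood at 0.06 ± 0.12 (adjusted p = 0.832). Of the 30 genes in this list, 13 are also in other lists, so the lists are not independent. Calb2 is among them, as a thalamus and an immature neuron marker, so its rise cannot be assigned to interneurons alone. The rise came with lower dentate markers, at a mean of -0.69, and higher subicular markers, at 0.57.

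Genes of GABA synthesis, transport and breakdown changed in part. Among 17 genes, 8 rose, 1 fell and 8 did not pass, with a list median of 0.14, and adjusted over the list alone 9 were higher and 4 lower (camera adjusted p = 0.00475, upward; adjusted p = 0.314 with an estimated correlation). Gad1 and Gad2, the glutamate decarboxylases that make GABA, rose by 0.49 ± 0.09 (adjusted p = 0.00721) and 0.63 ± 0.11 (adjusted p = 0.00724). Both calls were lost with the dentate covariate, at 0.093 and 0.046 (adjusted p = 0.847 and 0.936). They were also lost with the choroid covariate, at 0.46 and 0.58 (0.479 and 0.477). Diet accounts for 78.6% and 81.3% of the variance of the dentate and choroid covariates, so neither loss tells tissue content from diet. Slc32a1, the vesicular GABA transporter, rose by 0.54 ± 0.11 (adjusted p = 0.0122). Slc6a13, a GABA transporter that the fibroblast list also holds, rose by 1.76 ± 0.23 (adjusted p = 0.00207). The member that fell was Slc12a2, a chloride importer, at -0.85 ± 0.17 (adjusted p = 0.0141). Without ketogenic 2 the calls of Slc32a1 (adjusted p = 0.0601) and Slc12a2 (0.0814) were lost, as was that of Slc12a2 without control 2 (0.0611), and with the choroid covariate Slc12a2 turned to 0.28 (0.598). The list missed the threshold on log2(FPKM + 1) values (adjusted p = 0.0533) and log2(FPKM + 0.1) values (adjusted p = 0.0963), and with marker genes of other lists left out (adjusted p = 0.0548).

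Among 19 genes of GABA receptor subunits and their scaffold, 5 rose and 2 fell, and adjusted over the list alone 6 were higher and 3 lower, with the list not past the camera test (adjusted p = 0.114). Gabra3 rose from 41.9 ± 1.61 to 94.1 ± 8.64 CPM, a log2 fold change of 1.17 ± 0.08 (adjusted p = 0.000196). Gabrq rose by 2.99 ± 0.51 (adjusted p = 0.00573), Gabrg1 rose by 0.60 ± 0.13 (adjusted p = 0.0158) and Gabrr2 fell by 1.64 on the log2 scale (adjusted p = 0.0128). The call of Gabrg1 was lost without control 2 (adjusted p = 0.0530) and without ketogenic 2 (adjusted p = 0.0890). These libraries also differed in interneuron markers, with a list mean of 0.69.

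Markers of hippocampal subfields moved in different directions. Of 18 dentate granule cell markers 8 fell and none rose, and adjusted over the list alone 15 were lower (camera adjusted p = 5.24e-11; adjusted p = 0.303 with an estimated correlation). Prox1, the transcription factor that sets granule cell identity, fell from 145.3 ± 16.2 to 88.7 ± 15.2 CPM (adjusted p = 0.00561). Lct fell by 2.21 (adjusted p = 0.00631), Fam163b by 0.99 (adjusted p = 0.00639) and Ahcyl2 by 0.40 (adjusted p = 0.00602). Of 18 markers of fields CA2 and CA3, 9 fell and 2 rose, and adjusted over the list alone 10 were lower and 3 higher (camera adjusted p = 1.35e-05; adjusted p = 0.181 with an estimated correlation). Prkcd fell by 1.48 (adjusted p = 0.000214), Bok by 0.80 (adjusted p = 0.00148), Map3k15 by 1.86 (adjusted p = 0.00324) and Cdh24 by 0.90 (adjusted p = 0.00427). Nptx1, the most abundant of these markers, fell by 0.42 (adjusted p = 0.00847), and Ptpn5 stood at 0.33 (adjusted p = 0.0631). Without ketogenic 2 the calls of Ahcyl2 (adjusted p = 0.0504) and Nptx1 (adjusted p = 0.0572) were lost, and without ketogenic 1 the log2 fold change of Lct was -2.98.

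The 15 CA1 markers split, with 4 higher and 5 lower, 4 and 8 adjusted over the list alone, and a camera adjusted p of 0.403. Nov rose by 1.305 ± 0.13 (adjusted p = 0.000929) and Dcn by 2.46 ± 0.28 (adjusted p = 0.00134), while Epha6 fell by 0.87 (adjusted p = 0.000541) and Neurod6 by 0.57 (adjusted p = 0.00887). Itpka and Mpped1, the most abundant of these markers, stood at -0.47 and 0.33 (adjusted p = 0.0316 and 0.0156). The call of Neurod6 was lost without ketogenic 2 (adjusted p = 0.0573), that of Mpped1 without control 2 or ketogenic 2 (up to 0.0929) and that of Itpka without any library but control 3 (up to 0.105). With the choroid covariate Itpka turned to 0.070 (adjusted p = 0.950).

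Of 18 subicular and cortical markers 6 rose and none fell, and 10 were higher adjusted over the list alone (camera adjusted p = 9.32e-06; adjusted p = 0.314 with an estimated correlation). Etv1 rose by 0.83 ± 0.11 (adjusted p = 0.00187), Fezf2, a deep-layer transcription factor, by 0.68 ± 0.10 (adjusted p = 0.00356), Ctgf by 1.56 ± 0.27 (adjusted p = 0.00665) and Nxph4 by 1.58 ± 0.29 (adjusted p = 0.00845). The most abundant members, Lmo3 and Rasgrf2, stood at -0.12 and -0.10 (adjusted p = 0.453 and 0.583). The list missed the threshold with fry (adjusted p = 0.0515) and with the choroid covariate (0.485). Of 18 thalamus and habenula markers 7 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.314 with an estimated correlation). They include Calb2 and Prkcd, given above, Cacna1g, a T-type calcium channel gene that rose by 0.78 ± 0.07 (adjusted p = 0.000541), and Ntng1, which rose by 0.64 ± 0.13 (adjusted p = 0.0134). Adarb1, the most abundant of them, stood at -0.14 (adjusted p = 0.264). The thalamus list missed the threshold on log2(FPKM + 1) values (adjusted p = 0.0528), on log2(FPKM + 0.1) values (0.0519), with control 1 and 2 left out (0.137), and with the choroid and dentate covariates (0.485 and 0.182), and the call of Ntng1 was lost without ketogenic 2 (0.0824).

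**Figure D2:**
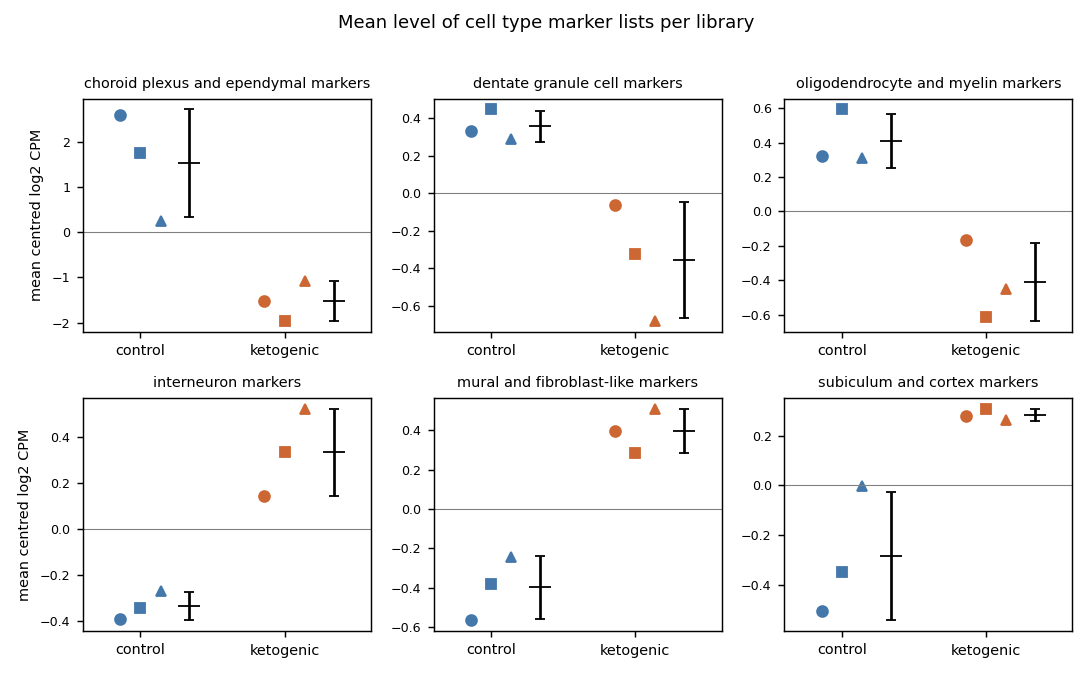
Mean of the centred log2 CPM over the genes of 6 marker lists (vertical axes, log2 scale, own range per panel) in each control and ketogenic library, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean and SD (n = 3). The choroid plexus mean ranges from 0.24 to 2.59 among the control libraries, and the dentate mean from -0.68 to -0.06 among the ketogenic libraries.

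The largest falls were in choroid plexus genes. The 10 largest falls under the naming rule were those of Tmem72, Steap1, Slc4a5, Aqp1, Ttr, Kcne2, Mfrp, Folr1, Clic6 and F5, with log2 fold changes between -6.77 and -4.45 and adjusted p between 0.00147 and 0.00442. Ttr, the transthyretin gene and an abundant transcript of choroid plexus epithelium, had 6442, 3373 and 704 CPM in the control libraries and 58.7, 28.5 and 67.2 CPM in the ketogenic libraries. Enpp2, abundant in choroid plexus and also listed with myelin, fell from 1492 ± 1149 to 117.4 ± 18.9 CPM, a log2 fold change of -3.67 ± 0.54 (adjusted p = 0.00300). Of 23 choroid plexus and ependymal markers 18 fell and none rose, and adjusted over the list alone 19 were lower (camera adjusted p = 3.35e-23; adjusted p = 0.303 with an estimated correlation, and 0.0821 with fry). Without control 1 the log2 fold changes were smaller, at -5.95 for Tmem72, -5.68 for Steap1, -5.33 for Slc4a5, -5.31 for Aqp1, -5.31 for Ttr, -4.46 for Kcne2, -4.63 for Mfrp, -4.51 for Folr1, -3.85 for Clic6, -3.66 for F5 and -2.93 for Enpp2. They were larger for Steap1 without ketogenic 1, at -7.49, and without ketogenic 3 for Tmem72, at -7.66, and Slc4a5, at -6.90.

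Most myelin markers fell as well. Of 24 oligodendrocyte and myelin markers 18 fell and none rose, and adjusted over the list alone 21 were lower (camera adjusted p = 6.70e-26; adjusted p = 0.30 with an estimated correlation). Mbp, which encodes myelin basic protein, fell from 2945 ± 257 to 1498 ± 217 CPM, a log2 fold change of -0.98 ± 0.10 (adjusted p = 0.00110). Mobp fell by 1.101 (adjusted p = 0.00147), Cldn11 by 0.86 (adjusted p = 0.00186) and Myrf by 0.74 (adjusted p = 0.00186). Among 14 oligodendrocyte precursor markers 1 rose and 1 fell, 3 and 1 adjusted over the list alone (camera adjusted p = 0.990, with fry pointing the other way). These were Pcdh15 at 0.75 ± 0.16 (adjusted p = 0.0158) and Sox10 at -0.66 ± 0.10 (adjusted p = 0.00333), while the abundant Tnr and Olig1 stood at -0.04 and -0.13 (adjusted p = 0.699 and 0.441). The call of Pcdh15 was lost without control 2 (adjusted p = 0.0627).

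Of 21 mural and fibroblast-like markers 11 rose and none fell, and 15 were higher adjusted over the list alone (camera adjusted p = 9.11e-13; adjusted p = 0.181 with an estimated correlation). Dcn, which encodes decorin and is also a CA1 marker, rose from 16.9 ± 4.86 to 92.6 ± 33.5 CPM (adjusted p = 0.00134). Col1a2, a collagen gene, rose by 1.31 ± 0.16 (adjusted p = 0.00158) and Vtn, a pericyte marker, by 0.77 ± 0.10 (adjusted p = 0.00202), while Rgs5, the most abundant gene of the list, stood at 0.29 ± 0.09 (adjusted p = 0.0840).

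The 10 largest rises under the naming rule were those of H2-Q1, Vgll3, Trhr, Dio3, Dlk1, Wnt6, Ecel1, Mpzl2, Gpr139 and Gabrq, with log2 fold changes between 2.99 and 4.07 and adjusted p between 0.00137 and 0.0213. These genes were scarce in the control libraries, at 0.181 to 1.90 CPM on average. Trhr, the thyrotropin-releasing hormone receptor gene, rose from 1.02 ± 0.649 to 14.4 ± 7.48 CPM, and Dio3, which encodes a deiodinase that inactivates thyroid hormone, from 0.896 ± 0.471 to 11.8 ± 7.37 CPM. H2-Q1 belongs to a family of near-identical histocompatibility genes that can share reads, so its value is uncertain. The log2 fold change of Ecel1 was 1.89 without ketogenic 3, and its call was lost without control 1 (adjusted p = 0.0577) or control 2 (0.0889), with -0.44 under the dentate covariate (0.896), while Gpr139 lost its call without ketogenic 2 (0.0646) or ketogenic 3 (0.0541). Without control 1 Vgll3 stood at 4.50, and without control 3 Trhr and Gpr139 stood at 4.45 and 4.86.

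Genes of ketone and fat metabolism changed in a few members. Of 13 ketone body genes 2 rose and none fell, and 3 were higher adjusted over the list alone (camera adjusted p = 0.230; fry adjusted p = 0.0412). Slc16a1, which encodes a transporter of ketone bodies and lactate, rose by 0.43 ± 0.08 (adjusted p = 0.01004), and Aacs stood at 0.30 ± 0.10 (adjusted p = 0.0784). Of 37 genes of fatty acid oxidation and PPAR-alpha targets 4 rose and 3 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.990, with a mean of 0.05 and a median of -0.05). The rises include Cd36 at 2.17 ± 0.36 (adjusted p = 0.00544), Angptl4 at 1.35 ± 0.31 (adjusted p = 0.0218) and Ppargc1a at 0.44 ± 0.10 (adjusted p = 0.0222). The calls of Angptl4 and Ppargc1a were each lost without control 2, ketogenic 2 or ketogenic 3 (adjusted p up to 0.0831 and 0.108), and that of Slc16a1 without control 2 or ketogenic 2 (up to 0.0699).

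Of 24 sterol synthesis and uptake genes 5 rose and none fell, and 8 were higher adjusted over the list alone (camera adjusted p = 4.43e-05; adjusted p = 0.492 with an estimated correlation and 0.106 with fry). Stard4 rose by 0.64 (adjusted p = 0.0218), Sqle by 0.45 (adjusted p = 0.0282), Msmo1 by 0.60 (adjusted p = 0.0309) and Fdft1 by 0.44 (adjusted p = 0.0412). All 4 lost the call without ketogenic 2 or ketogenic 3, Stard4, Msmo1 and Fdft1 without control 2, Msmo1 and Fdft1 without ketogenic 1 and Sqle without control 1, with adjusted p up to 0.0859, 0.0991, 0.0949 and 0.121 in the order named above. The myelin markers in the same libraries, Enpp2 among them, had a mean of -0.83 and a median of -0.76.

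Mitochondrially encoded transcripts took 4.70%, 4.44% and 4.63% of the counts in the control libraries and 5.34%, 5.04% and 5.07% in the ketogenic libraries. Their list passed the camera test upward (adjusted p = 0.00398; adjusted p = 0.381 with an estimated correlation), though 1 of 12 members rose and none fell, and 2 were higher adjusted over the list alone. It was mt-Nd4l, at 1.24 ± 0.15 (adjusted p = 0.00147), which overlaps a neighbouring gene so that its count is uncertain. Next by p were mt-Nd1, mt-Nd2 and mt-Nd6, at 0.21, 0.17 and 0.21 (adjusted p = 0.0682, 0.0974 and 0.160). The list call was lost without control 3 (adjusted p = 0.160), without ketogenic 1 (0.156) and with fry (0.0515).

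Of 54 nuclear genes of the respiratory chain 1 rose, Atp5o at 0.23 ± 0.06 (adjusted p = 0.0400), and adjusted over the list alone none was higher (camera adjusted p = 0.929). With edgeR none of 20 citric acid cycle genes passed, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 1 passing with DESeq2 (camera adjusted p = 0.761). Likewise none of 16 fatty acid synthesis genes passed, with 2 at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom (camera adjusted p = 0.990, upward, with a mean of -0.04), and none of 50 cytosolic ribosomal protein genes, with 4 at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom (camera adjusted p = 0.647). Among 26 gene IDs of 25 glycolysis and glucose transport symbols, with Aldoa under 2 IDs, 1 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.397). These were Pdk1 at 0.32 ± 0.08 and Pfkl at -0.29 ± 0.07 (adjusted p = 0.0293 each). The call of Atp5o was lost without any library but control 3 (adjusted p up to 0.165), that of Pdk1 without any but control 1 (up to 0.119) and that of Pfkl without control 1, control 2, ketogenic 2 or ketogenic 3 (up to 0.115).

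Synaptic genes changed in both directions. Of 24 glutamate receptor subunit genes 9 rose and 5 fell, 10 and 8 adjusted over the list alone (camera adjusted p = 0.0373; adjusted p = 0.303 with an estimated correlation). Grin3a, an NMDA receptor subunit gene, rose by 1.40 ± 0.09 (adjusted p = 0.000196), Grik1 by 0.90 ± 0.14 (adjusted p = 0.00348), Gria4 by 0.68 ± 0.10 (adjusted p = 0.00354) and Grm8 by 1.27 ± 0.20 (adjusted p = 0.00356). Of 27 synaptic vesicle and release genes 6 rose and 1 fell, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.606 with an estimated correlation). Unc13c rose by 1.41 ± 0.17 (adjusted p = 0.00151), Syt5 by 0.34 ± 0.06 (adjusted p = 0.00780) and Rims2 by 0.37 ± 0.08 (adjusted p = 0.0157), and Unc13a fell by 0.28 (adjusted p = 0.0256). Without ketogenic 2 the calls of Syt5 (adjusted p = 0.0620), Rims2 (0.0879) and Unc13a (0.119) were lost, and those of Rims2 and Unc13a also without control 2 (0.0700 and 0.114) and ketogenic 3 (0.0542 and 0.0821). The glutamate list lost its call without control 1 (adjusted p = 0.0965), without ketogenic 1 (0.0803), with limma-voom (0.275), on both FPKM scales (0.314 and 0.269), with control 1 and 2 left out (0.282) and with marker genes left out (0.0548). The vesicle list lost it without control 1 (0.0652), without control 2 (0.0502), on log2(FPKM + 0.1) values (adjusted p = 0.0753), with fry (0.106) and with control 1 and 2 left out (0.508), and interneuron markers had a mean of 0.69 in the same libraries.

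Of 17 neurogenesis and immature neuron markers 2 rose and none fell, and 3 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00811; adjusted p = 0.314 with an estimated correlation). These were Calb2, which mature interneurons also express, and Dcx, the doublecortin gene, at 0.51 ± 0.11 (adjusted p = 0.0154). Pcna stood at -0.29, Tubb3 at 0.37 and Stmn2 at 0.23 (adjusted p = 0.0731, 0.0812 and 0.176). The list call was lost without control 2 (adjusted p = 0.0850), without ketogenic 1 (0.0649), with limma-voom (0.134), on both FPKM scales (0.143 and 0.194), with fry (0.0694) and with control 1 and 2 left out (0.468), and that of Dcx without control 2 (0.0634) or ketogenic 2 (0.0867).

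**Figure D3:**
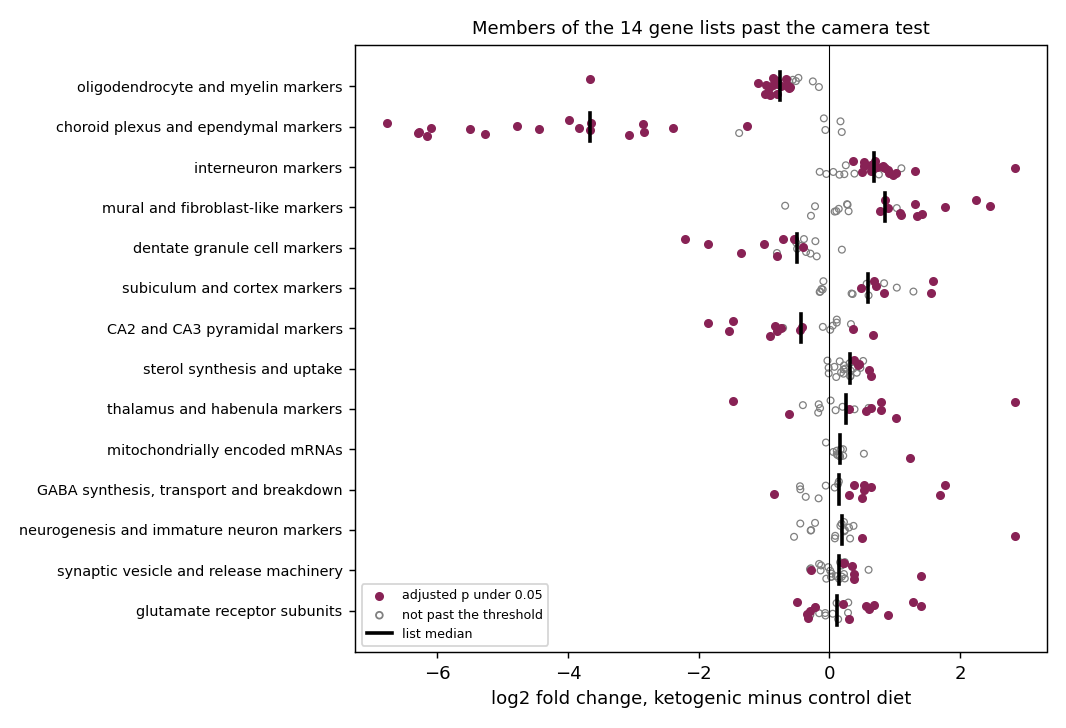
Log2 fold change, ketogenic minus control diet (horizontal axis), of each tested member of the 14 gene lists past the camera test. Filled points are genes with an adjusted p under 0.05, open points are the others and the black line is the list median, which runs from -3.67 in the choroid plexus list to 0.85 in the fibroblast list.

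In all, 14 of 42 lists passed camera with its preset correlation of 0.01, 10 upward and 4 downward. None of the 42 passed camera with an estimated correlation, where 6 had an unadjusted p under 0.05, and fry called 10, of which 8 were among the 14. The other lists were those of sodium and calcium channels, downward, and of ketone body synthesis, use and transport, upward (fry adjusted p = 0.0412 each; camera adjusted p = 0.176 and 0.230). Fits with the choroid plexus or the dentate mean as a covariate, chosen after seeing the data, ended further calls, where the loss of a list under its own mean (choroid plexus 0.598, dentate 0.921) is set by construction. With the choroid covariate the others were the sterol (adjusted p = 0.876), thalamus (0.485), GABA synthesis (0.176), neurogenesis (0.876) and glutamate receptor (0.876) lists, while the subiculum and synaptic vesicle lists turned downward (0.485 each). With the dentate covariate they were the thalamus (adjusted p = 0.182), GABA synthesis (0.445), neurogenesis (0.0688), synaptic vesicle (0.744) and glutamate receptor (0.182) lists.

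Markers of other cell types changed in fewer members. Of 20 astrocyte markers 1 rose, Agt at 1.03 ± 0.16 (adjusted p = 0.00351), also 1 adjusted over the list alone (camera adjusted p = 0.413), and the abundant Slc1a2 and Glul stood at -0.07 and -0.17 (adjusted p = 0.579 and 0.144). Of 22 microglia and macrophage markers 2 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.25). These were F13a1 at 1.59 ± 0.23 (adjusted p = 0.00279) and Mrc1 at 1.49 ± 0.28 (adjusted p = 0.00992), known from macrophages at the brain's borders, while Csf1r stood at -0.07 (adjusted p = 0.636). Among 20 endothelial markers 1 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.809). These were Itm2a at 0.50 ± 0.10 (adjusted p = 0.0126) and Ocln at -0.52 ± 0.11 (adjusted p = 0.0181), with Bsg and Slc2a1 at -0.19 and 0.05 (adjusted p = 0.141 and 0.907). With edgeR none of 8 blood cell markers passed, nor at an unadjusted p under 0.05, and 0 passed with DESeq2 or limma-voom (camera adjusted p = 0.809), with Hbb-bs at -0.35 and Hba-a1 at -0.58 (adjusted p = 0.606 and 0.449). The call of Itm2a was lost without control 2 (adjusted p = 0.0625) and that of Ocln without control 1, control 2 or ketogenic 2 (up to 0.0977).

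Of 17 striatum markers 5 rose and 3 fell, 5 and 4 adjusted over the list alone (camera adjusted p = 0.391). Among them were Meis2 at 0.58 ± 0.10 (adjusted p = 0.00726), Adcy5 at 0.47 ± 0.08 (adjusted p = 0.00732), Tac1 at 1.31 ± 0.26 (adjusted p = 0.0115) and Ppp1r1b at -1.12 ± 0.21 (adjusted p = 0.00976), with the abundant Gng7 at -0.12 (adjusted p = 0.427). Of 26 listed retina markers 6 had enough counts to test, and 1 fell, Arr3 at -1.42 ± 0.39 (adjusted p = 0.0452), also 1 adjusted over the list alone (camera adjusted p = 0.203), with Rlbp1 at -0.30 and Rom1 at -0.35 (adjusted p = 0.304 and 0.533). Meis2 and Ppp1r1b lost the call without ketogenic 2 (adjusted p = 0.0513 and 0.0623), Ppp1r1b turned to 0.089 with the choroid covariate (0.957), and Arr3 lost it without any library but ketogenic 2 (up to 0.160).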

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

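The fits with a covariate, with control 1 and 2 left out and with marker genes left out are tests chosen only after the results were seen, and the other alternatives were planned. The cause of a change was not tested unless one is named. The count of 1593 genes stayed within 1.5 times in 12 alternatives, from 1096 to 2365. It was 2462 without a filter (1252 higher, 1210 lower), where 30524 genes were tested, 1060 on log2(FPKM + 1) values (480 lower) and 823 at a fold change of at least 1.5 (512 higher, 311 lower), a stricter threshold. On log2(FPKM + 0.1) values 504 genes were lower. With 1 library left out, and so fewer samples, the count ran from 538 to 1877, with 324 to 936 higher and 214 to 941 lower. It was 289 with control 1 and 2 left out (133 higher, 156 lower), 12 with the choroid plexus mean as a covariate (6 higher, 6 lower) and 1 with the dentate mean as a covariate (1 higher and 0 lower, edgeR). At an unadjusted p under 0.05 there were 3803 genes without a covariate, 1712 with the choroid covariate and 1515 with the dentate covariate. Diet accounts for 81.3% and 78.6% of the variance of these covariates, which leaves little of the diet difference to test. Depth of 16832240 to 18357792 counts per library limits what can be said of scarce genes.

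Erbb4 ran from 0.51 to 0.80 with 1 library left out, and missed the threshold at 0.54 on log2(FPKM + 1) values. It also missed it at 0.69 with the choroid covariate (adjusted p = 0.457), where its standard error went from 0.13 to 0.30, at 0.041 with the dentate covariate (adjusted p = 0.966, standard error 0.18), where the fold itself shrank, and at 0.66 with control 1 and 2 left out (adjusted p = 0.137). Nrg1 ran from 0.71 to 1.05 with 1 library left out. It missed the threshold at 0.85 with limma-voom, at 0.27 on log2(FPKM + 1) values, where the pseudocount shrinks the folds of scarce genes, and at 0.70 on log2(FPKM + 0.1) values. It also missed it at 0.72 with the choroid covariate (adjusted p = 0.715), where its standard error went from 0.23 to 0.55, at 0.19 with the dentate covariate (adjusted p = 0.929, standard error 0.44) and at 0.83 with control 1 and 2 left out (adjusted p = 0.280). With marker genes left out, which does not change their own counts and cannot test tissue content, both kept the call, Erbb4 at 0.65 and Nrg1 at 0.87 (adjusted p = 0.0106 and 0.0383). Over the 15 alternatives set beforehand the adjusted p ran from 2.32e-09 to 0.0659 for Erbb4 and from 0.00309 to 0.146 for Nrg1, with the lowest of each from the fit without a filter.

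The number of lists past the camera test, 14, became 9 on log2(FPKM + 0.1) values, 7 with marker genes left out, of which 6 were among the 8 of the 14 that could be tested, and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05. It ran from 11 to 16 with 1 library left out, with 11 to 14 of the 14 kept. With the choroid covariate the subiculum and cortex list and the synaptic vesicle list turned downward (adjusted p = 0.485 each) and another 6 of the 14, the thalamus and GABA synthesis lists among them, lost their call (adjusted p = 0.485 and 0.176 for these), as did 6 with the dentate covariate (adjusted p = 0.182 and 0.445 for these). In each fit 1 of the 6 is the list whose own mean is the covariate, which must lose its call. In all 12 lists passed with the choroid covariate and 13 with the dentate covariate, of which 6 and 8 were among the 14, and with control 1 and 2 left out 14 passed, of which 10 were among the 14. There was no clear sign that the replicate numbers pair the libraries. Deviations of same-numbered libraries from their diet means correlated at -0.024, 0.061 and 0.029. Control 3 and ketogenic 2 correlated best with their own number and the other libraries did not. These values cannot exclude a shared litter, cage or day. With the replicate block 1504 genes and 17 lists passed, with Erbb4 at 0.63 (adjusted p = 0.00857) and Nrg1 at 0.86 (adjusted p = 0.0283).

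Among single genes the direction turned as follows. With the choroid covariate the log2 fold change was 0.14 for Erbb3, 0.10 for Clic6, 0.10 for Enpp2, 0.089 for Ppp1r1b, 0.070 for Itpka, 0.11 for Erbin, 0.066 for Nrg2, -0.017 for Nrg3, 0.84 for Erbb2, -0.56 for Cck, -0.63 for Slc2a1, 0.034 for Bsg, 0.026 for Tnr, -0.021 for Rgs5, 0.10 for Lmo3, -0.14 for Stmn2, -0.26 for Tubb3, 1.13 for Rom1 and 0.28 for Slc12a2. With the dentate covariate it was -0.44 for Ecel1, -0.047 for Aacs, 0.059 for Slc1a2, 0.35 for Hbb-bs, 0.15 for Hba-a1, -0.46 for Slc2a1, 0.011 for Bsg, 0.14 for Lmo3, 0.28 for Rlbp1, 0.076 for Rom1, 0.24 for Gng7, -0.88 for Htr2c, -0.072 for Lypd1, -0.14 for Gsg1l and -0.53 for Coch. With control 1 and 2 left out it was 0.20 for Erbb2, -0.20 for Cck, -0.33 for Slc2a1 and 0.38 for Rom1. With 1 library left out, genes that did not pass ran across 0: Erbb2 from -0.31 to 0.061, Cck from -0.048 to 0.21, Slc2a1 from -0.11 to 0.28, Rom1 from -0.61 to 0.017, Htr2c from -0.32 to 0.52, Gsg1l from -0.078 to 0.18 and Coch from -0.10 to 0.24.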

Other observations

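The tests of choroid plexus transcripts, of subicular markers with the choroid covariate, of structure among libraries of the same diet and of the ratios of Erbb4 and Nrg1 to interneuron genes were chosen only after the results were seen. The lists of ventral and dorsal hippocampus markers were also added after seeing the data. Ion channel genes changed in both directions. Of 27 sodium and calcium channel genes 4 rose and 8 fell, 6 and 9 adjusted over the list alone (camera adjusted p = 0.176, downward, and fry adjusted p = 0.0412, with a mean of -0.06 and a median of 0.0003). Scn4b, a sodium channel beta subunit gene, fell by 1.27 (adjusted p = 0.000214), Cacna1h by 0.52 (adjusted p = 0.00207) and Cacna1a by 0.48 (adjusted p = 0.00232). Of 28 potassium and HCN channel genes 7 rose and 7 fell, 9 and 7 adjusted over the list alone (camera adjusted p = 0.778, downward, with a mean of 0.04 and a median of -0.04). Kcnk1 fell by 0.71 (adjusted p = 0.00109) and Kcnj6 by 0.66 (adjusted p = 0.00128), and Kcnt1 rose by 0.63 (adjusted p = 0.00368). Of 16 genes of adenosine signalling and ATP-sensitive potassium channels 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.25). These were Abcc8 at -0.69 (adjusted p = 0.00353) and Kcnj11 at -0.47 (adjusted p = 0.0181), which encode both subunits of a neuronal channel. The call of Kcnj11 was lost without control 2, ketogenic 2 or ketogenic 3 (adjusted p up to 0.0938). Dentate markers had a mean of -0.69 in the same libraries.

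Of 23 growth factor and neuropeptide genes 6 rose and 2 fell, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0562), among them Sst and Nptx1, given above, Tac1 at 1.31 (adjusted p = 0.0115) and Adcyap1 at 2.04 (adjusted p = 0.0131). Of 29 immediate early genes 3 rose and 3 fell, 4 and 5 adjusted over the list alone (camera adjusted p = 0.761). Cyr61 rose by 1.19 (adjusted p = 0.00356), while Npas4 fell by 0.84 (adjusted p = 0.00492), Ptgs2 fell by 0.50 (adjusted p = 0.0135) and Arc fell by 0.48 (adjusted p = 0.0206). Of 20 inflammatory and glial activation genes 3 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.507, upward, with a mean of 0.14 and a median of -0.14). Lyz2 rose by 1.02 (adjusted p = 0.00197), Spp1 by 2.24 (adjusted p = 0.00347) and Cd44 by 2.24 (adjusted p = 0.00569), beside fibroblast-like markers with a mean of 0.77. Of 23 integrated stress response genes 2 rose and 2 fell, 3 and 2 adjusted over the list alone (camera adjusted p = 0.266). They were Slc7a11, the cystine transporter gene, at 0.92 (adjusted p = 0.000196), Cebpb at -0.72 (adjusted p = 0.00656), Psat1 at -0.36 (adjusted p = 0.0184) and Nupr1 at 1.122 (adjusted p = 0.0195). Slc7a11 was also the member that rose among 20 NRF2 targets, over all genes and adjusted over the list alone (camera adjusted p = 0.397). Of 25 glucocorticoid-responsive genes 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.397), namely Nr3c2 at -0.49 (adjusted p = 0.00401), Cebpd at -0.66 (adjusted p = 0.0189) and Klf9 at -0.35 (adjusted p = 0.0384). Of 24 chaperone genes 2 fell, 1 adjusted over the list alone (camera adjusted p = 0.176), Sdf2l1 at -0.88 (adjusted p = 0.0290) and Cryab at -0.45 (adjusted p = 0.0490). Of 19 circadian clock genes 2 rose, 2 and 1 lower adjusted over the list alone (camera adjusted p = 0.929, upward, with a mean of 0.04 and a median of -0.05), Npas2 at 0.84 (adjusted p = 0.0113) and Hlf at 0.24 (adjusted p = 0.0434). Without control 2 or ketogenic 2 the calls of Adcyap1, Ptgs2, Arc, Psat1, Nupr1, Cebpd, Klf9, Cryab, Npas2 and Hlf were lost, with adjusted p up to 0.0744, 0.0802, 0.0800, 0.105, 0.0694, 0.1003, 0.155, 0.152, 0.0660 and 0.202 in this order. Those of Arc, Nupr1, Cebpd, Klf9 and Hlf were also lost without ketogenic 3 (adjusted p = 0.0521, 0.0721, 0.0686, 0.0617 and 0.106), those of Klf9 and Cryab without control 3 (0.0855 and 0.0842) and ketogenic 1 (0.0860 and 0.0913), and those of Cryab and Hlf without control 1 (0.0707 and 0.135). Sdf2l1 lost its call without control 3, ketogenic 1 or ketogenic 2 (adjusted p up to 0.135).

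Choroid plexus transcripts were lower in the ketogenic libraries, and they also differed among the control libraries. Over 18 choroid plexus genes the median log2 ratio of control 1 to control 3 was 3.01, 8.08-fold, with an SD among genes of 0.64, as unequal carry-over of a single tissue in dissection could give. An effect of the diet on these genes cannot be told apart from this, since the median gap between the lowest control and the highest ketogenic library, 1.72, was smaller than the range of 3.01 among controls. With the choroid plexus mean as a covariate the dentate list had a mean of -0.71 against -0.69 without it (camera with its preset correlation, adjusted p = 5.89e-08). Its size did not shrink, but diet accounts for 81.3% of the covariate's variance. This fit therefore cannot exclude carry-over as a cause of the dentate difference. The subiculum and cortex list went from 0.57 to -0.00096 (adjusted p = 0.485) with this covariate, and since diet accounts for 81.3% of the covariate's variance, carry-over and diet cannot be told apart for these markers.

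Lower dentate, CA3 and myelin markers with higher subicular, interneuron and fibroblast markers could come from a larger share of ventral hippocampus in the ketogenic samples. This explanation was raised after other genes of the same 6 libraries had been seen, so markers not yet seen are no independent test of it. Ventral markers listed before their values were seen had a median log2 fold change of 0.79, with 6 of 6 above 0 and 4 past the threshold (camera p = 7.61e-07, and 0.0305 with an estimated correlation), Nnat at 1.67, Nr2f2 at 1.77, and Lypd1 and Gpc3, which lost the call without control 1, ketogenic 2 or ketogenic 3, Lypd1 also without control 2 and Gpc3 without control 3 (adjusted p up to 0.157 and 0.118), with Lypd1 at -0.072 under the dentate covariate. Htr2c, also among the 6, stood at 0.022 and below 0 without control 2, control 3, ketogenic 2 or ketogenic 3 (-0.012, -0.32, -0.10 and -0.14). But it is also expressed in choroid plexus, and its control values of 88.2, 53.4 and 25.8 CPM fell in the order of the choroid plexus scores of 2.59, 1.75 and 0.24. Ketogenic 1, 2 and 3, at scores of -1.53, -1.96 and -1.09, had 35.5, 66.0 and 68.7 CPM. Of markers whose values had been seen when listed, 5 of 6 ventral ones were called higher, all but Coch at 0.11. Of the dorsal markers seen when listed, 4 of 4 were called lower. Among them, 4 ventral markers (Nov, Dcn, Calb2 and Coch) and 3 dorsal ones (Lct, Wfs1 and Iyd) are also in the lists fixed beforehand. Since all of these markers were listed with their values known, their tallies cannot test for a larger ventral share. Gsg1l, the 1 dorsal marker not seen before, stood at 0.015. Across genes, which are not independent replicates, the difference of a pair of ketogenic libraries correlated with the third minus the control mean at -0.058, 0.165 and 0.232, and for the control libraries at 0.312, 0.295 and -0.003, where deviations of libraries of different diets correlated between -0.118 and 0.068, so part of the spread within a diet may lie along the diet difference, and an effect of the diet on these cell types remains open and was not tested.

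Erbb4 may be higher because the ketogenic samples held more interneuron RNA. Its log2 ratio to the mean of Gad1, Gad2 and Slc32a1 was higher by 0.087 with a standard error of 0.07, against 0.65 for Erbb4 itself, which leaves this explanation open. The 2-sided exact permutation p of 0.3 does not show that the ratio was the same, and 3 libraries against 3 give no p below 0.1. For Nrg1 the difference was 0.30 with a standard error of 0.14 (2-sided exact permutation p = 0.2), and this explanation cannot be told apart from a change of Nrg1 itself because the diets overlap, with control 2 at -4.73 and ketogenic 1 at -4.79. An effect of the diet on either gene, within interneurons or in other cells, remains open and was not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real split, gave 1593 genes and the highest of the others 0 with edgeR, with 151 to 1077 genes at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05.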
